A study of Mus musculus with 12 samples.

How the data were processed

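RNA was measured by sequencing in C2C12 cells, an established mouse myoblast line that stops dividing and forms multinucleated myotubes when serum is reduced. There were 12 libraries in 4 groups of 3, with the replicates named A, B and C. The groups were proliferating myoblasts in growth medium at 0 h, control cells at 48 h of differentiation, cells differentiated for 48 h with TNF at 10 ng/ml, and cells at 48 h of differentiation in which Fbxl2 had been silenced by siRNA. TNF is an inflammatory cytokine and Fbxl2 encodes an F-box protein of an SCF ubiquitin ligase. Per the labels, total RNA was extracted and libraries were made with an Illumina mRNA kit. The labels name no separate cultures behind the replicates, so the p-values measure only the spread between these libraries, which may be technical. They also do not say whether the control or TNF cells received a non-targeting siRNA.

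The authors deposited a table of whole-number read counts for 21232 gene symbols in the 12 libraries, of which 4354 had no count in any library. Per the submitters' processing notes, CASAVA, DESeq2 and the mm10 genome build were used, with no versions. The aligner, the counting tool, its use of strand and the annotation are not given in the sources used here, so reads of near-identical copies, overlapping genes and antisense genes could not be told apart. The authors also deposited 3 tables of comparisons. Their expression columns held a normalized signal, the deposited counts divided by a single size factor per library, and listed genes with at least 10 counts summed over the libraries of the table. Their remaining columns held the authors' log2 fold changes, p-values and adjusted p-values, with DESeq2's column names per the file headers. The deposited table named for proliferation held log2 fold changes of TNF over proliferation, as found from its own expression columns: the median absolute difference was 0.001 for TNF over proliferation and 0.1864 for control over proliferation. In the deposited table for TNF, 23 gene symbols had been turned into dates. The counts table was used for every test, and the deposited comparisons only for a check of their direction and number of calls.

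Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Library totals ran from 26416978 to 32917763 counts, and 14303 to 14796 genes had a count in a library. A floor of 3 counts corresponded to 0.0911 to 0.114 CPM on the library totals, and the CPM values of genes were computed on the totals multiplied by the TMM factors. The 10 most abundant genes took 4.70% to 5.52% of the counts of a library. Intervals and floors cover counting error only, since the labels name no molecular identifiers. Genes were kept by filterByExpr, which left 12736. Libraries were scaled by TMM, a quasi-likelihood model with 4 group means and 8 residual degrees of freedom was fitted to all 12 libraries with robust dispersion estimates, and contrasts were tested with glmQLFTest and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The median tagwise biological coefficient of variation was 0.048. CPM values are given as mean ± SD over 3 libraries. Log2 fold changes are given with an approximate standard error (SE), the absolute log2 fold change divided by the square root of the F statistic. It can understate the error where a group holds few counts. Principal components were computed from log2 CPM with a prior count of 2.

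Replicates were compared before averaging. No pair of a group held identical values, and the chi-square statistic per degree of freedom between replicate counts ran from 1.62 to 22.2, where sampling alone gives 1. Pearson correlations of log2 CPM between replicates ran from 0.9937 to 0.9958.

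A total of 27 lists with 637 distinct genes was fixed, with 20 gene lists and 7 lists of cell type markers, as were the groups, the tests, the alternatives and the rule for named genes, before the data were examined. Of the list genes, 2 were absent from the counts table and 52 lay below the filter. For each list the members called higher and lower were counted over all genes tested and adjusted over the list alone. Lists were tested with camera at a preset inter-gene correlation of 0.01 and called at an adjusted p under 0.05 over the 27 lists of a comparison, and tested again with an estimated correlation. Among the calls, 4 of 15 held with the estimated correlation for differentiation, 2 of 16 for TNF, 1 of 12 for Fbxl2 siRNA and 2 of 11 for TNF against Fbxl2 siRNA. In the text, the second p is called the adjusted p with an estimated correlation. fry was run as an alternative that tests whether the genes of a list move, on balance, in a single direction.

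Genes were named by rule. In each comparison with the control group or of it, Fbxl2, Myod1, Myog, Mymk, Myh3, Ckm, Mki67, Cdkn1a and Nfkbia were reported whatever their result. The 5 genes with the largest rise and the 5 with the largest fall were added, among called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups, leaving out gene models without a proper symbol. For every called list, the 2 members with the smallest p in its direction were added. Of the genes named by this rule, 1 is not reported here. For TNF against Fbxl2 siRNA only the 5 largest rises and falls were named. Mymk is listed as Tmem8c and Mymx as Gm7325 in the counts table. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10, and 96.9% of the symbols in the counts table were found there.

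Comparisons that share the control libraries were set against 100 simulated draws in which all 12 libraries followed the control means. The fit was tested on simulated data with 200 genes changed by known folds, equally often up and down, with counts drawn independently for each gene. Far fewer genes changed there than were called in the data, so errors of scaling between libraries were not tested. In the simulated TNF comparison of 12725 genes, 39 of 50 genes changed 1.25-fold and 49 of 50 changed 2-fold were recovered, and 7 of 12525 unchanged genes were called. In the simulated Fbxl2 siRNA comparison of 12725 genes these counts were 37 of 50, 48 of 50 and 15 of 12525, and in the simulated differentiation comparison of 12725 genes they were 36 of 50, 47 of 50 and 9 of 12525.

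The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a fit to the 6 libraries compared, the replicate letter as a block, a term for letter A against letters B and C (the titles carry sequence numbers that set A apart), a threshold of 2-fold, and leaving out each replicate in turn or a whole letter.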

Results

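Gene expression was measured by RNA sequencing in C2C12 mouse myoblasts in 4 groups of 3 libraries, with library totals between 26416978 and 32917763 counts. The groups were proliferating myoblasts, control cells at 48 h of differentiation, cells differentiated for 48 h with 10 ng/ml TNF, and cells at 48 h of differentiation after Fbxl2 silencing. The title of the series concerns how TNF affects skeletal myogenesis through the Fbxl2 gene. The first principal component held 57.2% of the variance in log2 CPM and the second 23%. On the first, the proliferation libraries averaged -74.1 ± 4.43 (SD, n = 3), Fbxl2 siRNA -4.93 ± 4.28, control 38.3 ± 0.965 and TNF 40.7 ± 0.979. On the second, TNF libraries averaged 43.9 ± 1.63 and control libraries -31.4 ± 1.97. On the third, with 11.7% of the variance, Fbxl2 siRNA averaged -32.9 ± 2.45, outside proliferation (12.7 ± 1.10) and control (22.6 ± 1.55).

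**Figure D1:**
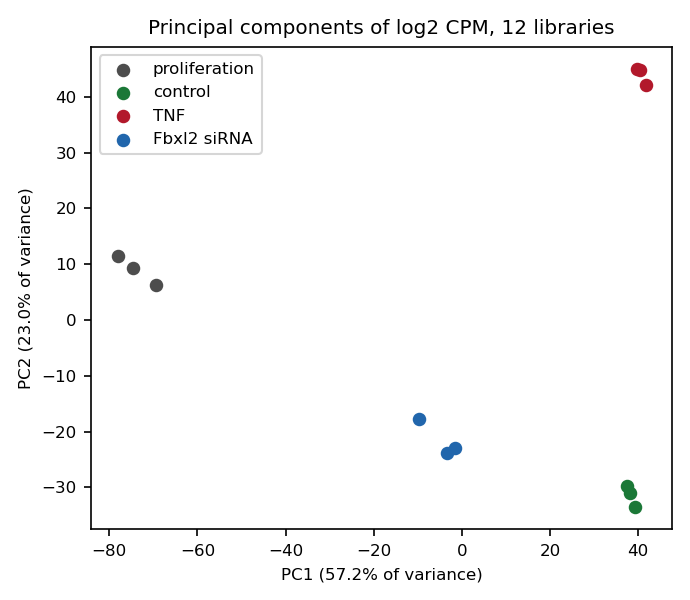
Principal components 1 and 2 (axes, with their percent of variance) of log2 CPM, with each of the 12 libraries as a point coloured by group. On the first component the Fbxl2 siRNA libraries lie between the proliferation libraries, at the left, and the control libraries, with the TNF libraries apart from control on the second component (group means 43.9 and -31.4).

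Fbxl2, the silenced gene, was examined first in every group. It is a protein-coding gene on the minus strand of chromosome 9 (GRCm38, 113963637 to 114046191). Its level was 26 ± 1.71 CPM (SD, n = 3) in proliferating myoblasts, 32.9 ± 1.30 in control, 28.9 ± 1.05 with TNF and 22.2 ± 1.52 after Fbxl2 siRNA. The siRNA libraries retained 67.5% of the control level (log2 fold change -0.57, 95% confidence interval -0.70 to -0.44, edgeR adjusted p = 1.67e-07), and each of them lay below each control library. Their level was also below that of proliferating myoblasts (log2 fold change -0.22, adjusted p = 0.0055). With TNF, Fbxl2 stood at 87.6% of control (log2 fold change -0.19, 95% confidence interval -0.32 to -0.06, adjusted p = 0.0137). That call ended without control replicate C (adjusted p = 0.0626), without TNF replicate A (adjusted p = 0.0629) or without all libraries of letter C (adjusted p = 0.0892), and the adjusted p ranged from 0.00123 to 0.0892 over 17 alternatives.

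**Figure D2:**
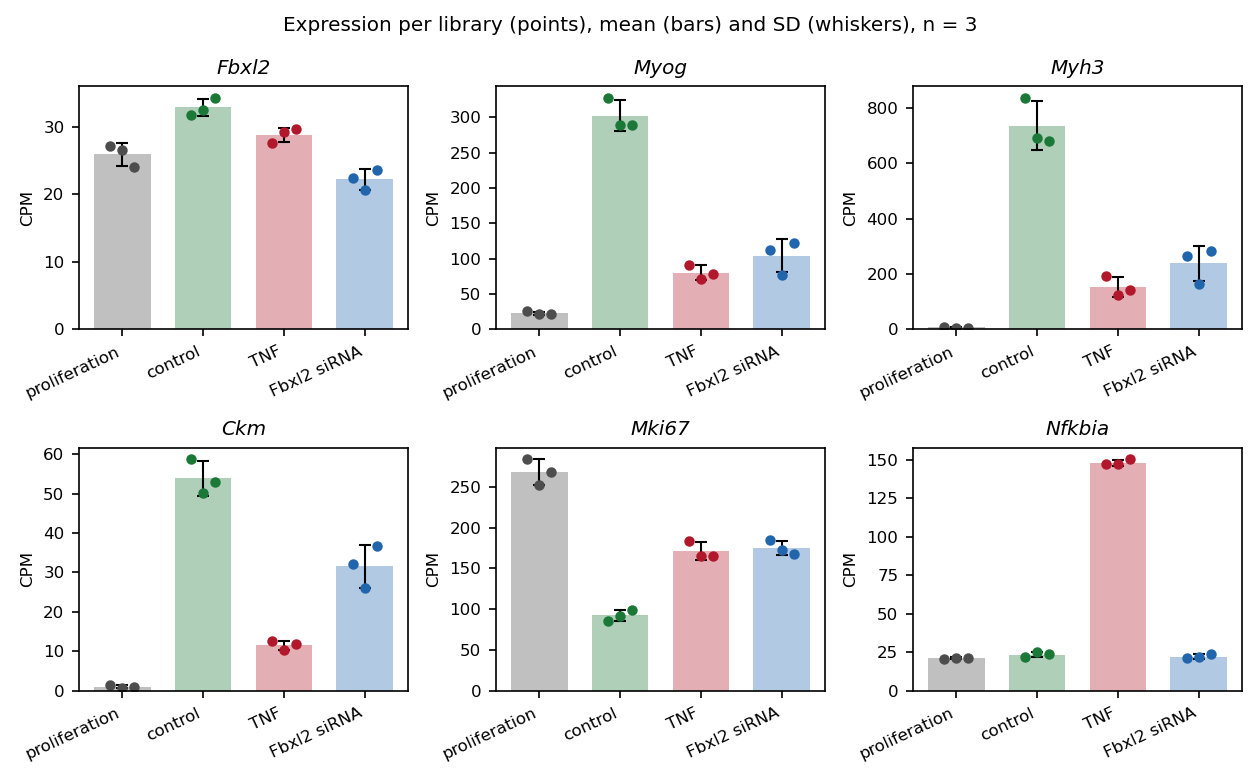
CPM (vertical axes, starting at 0) of Fbxl2, Myog, Myh3, Ckm, Mki67 and Nfkbia in the 4 groups, with points for libraries, bars for means and whiskers for SD (n = 3). Fbxl2 averaged 32.9 CPM in control and 22.2 in the Fbxl2 siRNA libraries, Myog rose from 22.5 to 302 CPM in differentiation and lay at 79.9 with TNF and 104 with Fbxl2 siRNA, and Nfkbia stood out at 148 CPM with TNF alone.

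The first comparison asked what changed between proliferation and 48 h of differentiation. Myh3, which encodes embryonic myosin heavy chain, went from 6.32 ± 1.08 CPM in proliferating myoblasts to 737 ± 88.2 in control (SD, n = 3), a 116-fold rise (log2 fold change 6.86, SE 0.32, adjusted p = 6.02e-08). The muscle creatine kinase gene Ckm rose 53.6-fold, from 0.992 ± 0.349 to 53.9 ± 4.40 CPM. The myogenic transcription factor Myog (chromosome 1, 134289989 to 134292548) rose 13.4-fold, from 22.5 ± 2.31 to 302 ± 22 CPM. Mymk, which encodes the membrane fusion protein myomaker, rose 30.7-fold, from 5.61 ± 0.988 to 173 ± 13.9 CPM. The proliferation marker Mki67 was 2.91-fold lower at 48 h, with 268 ± 16 CPM before and 92.3 ± 6.80 CPM after.

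The myogenic factor Myod1 rose less, by a log2 fold change of 0.38 (SE 0.05), and the cell cycle inhibitor gene Cdkn1a rose by 1.06 (SE 0.05). Nfkbia, which encodes an inhibitor of NF-kB, had a log2 fold change of 0.16 (SE 0.06, adjusted p = 0.0255). The adjusted p of Nfkbia ranged from 0.00628 to 0.147 over 17 alternatives, and the call was lost without proliferation replicate A (0.0775), control replicate B (0.132), control replicate C (0.0669), or all libraries of letter B (0.147) or letter C (0.105).

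Of 50 sarcomere genes tested, 47 were higher and 3 lower in control than in proliferation, with the same counts adjusted over the list alone. Their median log2 fold change was 4.78, or 4.58 with 2 members that had no count in a group set at their bound (camera adjusted p = 2.21e-19, adjusted p = 0.174 with an estimated correlation). The members with the smallest p were Tpm2, a tropomyosin gene (log2 fold change 1.45, SE 0.05), and Klhl40 (3.87, SE 0.15). Calcium handling and excitation coupling genes had 23 of 25 members higher and 1 lower (adjusted p = 3.5e-11, adjusted p = 0.174 with an estimated correlation), led by Rapsn, which clusters acetylcholine receptors (1.43, SE 0.05), and the ryanodine receptor gene Ryr3 (4.04, SE 0.14). In the fusion list, 13 of 18 members were higher and 3 lower (adjusted p = 0.000518, adjusted p = 0.286 with an estimated correlation), with log2 fold changes of 4.42 for Mymx, the myomixer gene, and 2.54 for Dysf, the dysferlin gene. Among 12 myogenic regulators, 9 were higher and 2 lower (adjusted p = 0.0171, adjusted p = 0.338 with an estimated correlation), with a log2 fold change of 1.06 for both Mef2a and Pax7. Extracellular matrix genes had 31 of 40 members higher and 6 lower (adjusted p = 9.5e-14, adjusted p = 0.112 with an estimated correlation).

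All 30 mitosis genes were lower, with a median log2 fold change of -1.94 (adjusted p = 5.93e-46, adjusted p = 0.0499 with an estimated correlation). Bub1b, a spindle checkpoint gene, was 4.27-fold lower and the condensin gene Ncapg 5.26-fold lower. All 36 DNA replication genes were lower as well, with a median of -1.56 (adjusted p = 1.26e-28, adjusted p = 0.0499 with an estimated correlation), among them the helicase subunit gene Mcm3 at 3.41-fold and Uhrf1 at 3.53-fold. Of 25 genes of the unfolded protein and stress response list, 19 were lower and 2 higher (adjusted p = 7.4e-06, adjusted p = 0.0499 with an estimated correlation). Its leading members were Psat1, which fell from 520 ± 19.7 to 104 ± 5.96 CPM, and Phgdh, from 347 ± 31.5 to 80.3 ± 2.43 CPM, and both encode enzymes of serine synthesis. Cholesterol synthesis genes were lower in 22 of 25 cases and higher in 1 (adjusted p = 0.000267, adjusted p = 0.367 with an estimated correlation), with log2 fold changes of -0.86 for Fdps and -1.43 for Pmvk.

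Of 44 interferon-stimulated genes tested, 43 were higher and 1 lower in control than in proliferation, with a median log2 fold change of 3.34 (adjusted p = 1.04e-35, adjusted p = 0.0794 with an estimated correlation). Gbp2 rose 10.2-fold, from 4.37 ± 0.482 to 45.0 ± 1.38 CPM, and Samd9l 6.87-fold. Oas2, an antiviral 2'-5' oligoadenylate synthetase gene, had no count in any proliferation library and 21.2 ± 3.49 CPM in control, which was at least 205-fold higher against a floor of 3 counts per library. In the list of MHC class I presentation, 20 of 21 genes were higher and 1 lower (adjusted p = 7.92e-09, adjusted p = 0.116 with an estimated correlation), including B2m at 3.19-fold and H2-K1 at 3.23-fold.

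Among the marker lists, all 7 smooth muscle genes tested were higher (median 2.28, adjusted p = 6.69e-11, adjusted p = 0.0174 with an estimated correlation), including Acta2 from 568 ± 5.06 to 2990 ± 74.4 CPM and Tagln from 100 ± 7.67 to 488 ± 20.5 CPM. These 2 genes belong to the extracellular matrix list too and were its leading members, and the lists share 3 genes. Fibroblast markers were higher in 7 of 8 cases (adjusted p = 0.00131, adjusted p = 0.0758 with an estimated correlation), with Dcn, the decorin gene, up 16.7-fold and Ly6a up 1.70-fold. Of 7 osteoblast markers, 4 were lower and 1 higher (adjusted p = 0.00499, adjusted p = 0.0758 with an estimated correlation). Spp1, the osteopontin gene, fell from 7230 ± 209 to 1130 ± 30.5 CPM and Phex was 6.04-fold lower, while the mean of the list was positive (0.04) and its median negative (-0.17). That mean included a highest log2 fold change of 7.4, and 1 member had no count in a group. The muscle atrophy and autophagy list had 14 of 25 members higher and 5 lower (adjusted p = 0.0443, adjusted p = 0.323 with an estimated correlation), with log2 fold changes of 1.27 for the ubiquitin ligase gene Fbxo32 and 1.49 for Map1lc3a. Its call was lost without the libraries of letter B (adjusted p = 0.0638) or letter C (adjusted p = 0.0511).

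Among the 5 largest rises, besides Oas2, were those of the matrix gene Cilp, from 0.236 ± 0.0772 to 152 ± 11.1 CPM, and of Ankrd2, from 0.0796 ± 0.0170 to 16.8 ± 1.22 CPM. The perinatal myosin gene Myh8 and the interferon-inducible GTPase gene Iigp1 rose by log2 fold changes of 7.21 and 7.29. Ankrd2, Myh8 and Iigp1 had only 7, 13 and 9 counts in total over the proliferation libraries, so the sizes of their rises are uncertain. The 5 largest falls included 3 proliferin genes, Prl2c3 (chromosome 13, 12790816 to 12800079), Prl2c2 and Prl2c5, with log2 fold changes of -7.21, -6.75 and -5.18. Reads of these near-identical copies could be divided among them, so their single values are uncertain. Their family of 4 listed genes summed to 675 ± 87.0 CPM in proliferating myoblasts and 5.17 ± 0.244 CPM in control. The others were Ngfr and Slco4a1, at 60.5-fold and 26.7-fold lower.

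No call was made for 12 lists. The counts higher and lower were 10 and 7 of 20 for muscle energy metabolism, 7 and 4 of 14 for cell cycle exit, 25 and 10 of 46 for NF-kB targets, 15 and 8 of 26 for repressors of myogenesis, 10 and 11 of 29 for genes related to Fbxl2, 9 and 9 of 21 for p53 targets, 15 and 10 of 27 for immediate early genes, and 8 and 11 of 26 for apoptosis. Among marker lists they were 8 and 4 of 12 for reserve or satellite cell markers, 2 and 2 of 4 for adipocyte markers, 2 and 1 of 5 for macrophage markers and 1 and 0 of 1 for endothelial markers. Mean, median and test differed in sign for p53 targets and immediate early genes. The counts of every list were the same when adjusted over the list alone. In all, edgeR called 9836 of 12736 genes, 4885 higher and 4951 lower in control, of which 1537 rose and 1051 fell at least 2-fold.

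The second comparison asked what TNF changed over 48 h of differentiation. The chemokine gene Ccl2 (chromosome 11, 82035571 to 82037453) went from 9.05 ± 1.02 CPM in control to 990 ± 22.2 with TNF (SD, n = 3), a 110-fold rise (log2 fold change 6.78, SE 0.07, adjusted p = 3.89e-24). The complement gene C3 went from 0.352 ± 0.158 to 753 ± 45.6 CPM, a log2 fold change of 11.07, with 31 counts in total over the control libraries. Nfkbia, itself a target of NF-kB, rose 6.31-fold, from 23.5 ± 1.64 to 148 ± 2.02 CPM. Myog was 3.78-fold lower, at 79.9 ± 10.6 CPM against 302 ± 22 in control (adjusted p = 9.46e-06). Myh3 was 4.8-fold lower, at 153 ± 35.9 against 737 ± 88.2 CPM.

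Ckm was 4.68-fold lower with TNF, Mymk 3.86-fold and Myod1 2.18-fold. Cdkn1a was 1.92-fold lower, while Mki67 was 1.86-fold higher, at 171 ± 10.8 CPM against 92.3 ± 6.80. Saa3, an acute phase gene, rose from 0.223 ± 0.0182 to 147 ± 17.5 CPM and Serpina3g from 0.231 ± 0.0754 to 61.7 ± 1.54 CPM. Cxcl11, a chemokine gene listed as a polymorphic pseudogene in GENCODE M21, had 1 count over the 3 control libraries. With TNF it had 12.3 ± 0.600 CPM, a ratio of 1100 (95% counting interval 197 to 43600). Tnip3 had 2 counts over the control libraries and 20.6 ± 1.09 CPM with TNF, a ratio of 927 (256 to 7660). The largest falls were those of the matrix genes Cilp (14.6-fold lower), Fbln7 (13.7-fold) and Prelp (8.48-fold), of Htra3, a secreted protease gene (9.23-fold), and of Myh8 (7.31-fold).

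Of 46 NF-kB targets tested, 45 were higher with TNF and 0 lower, also when adjusted over the list alone, with a median log2 fold change of 1.94. This call held with an estimated correlation (adjusted p = 6.1e-05). All 21 genes of MHC class I presentation were higher (median 1.46), and the call also held (adjusted p = 0.00542 with an estimated correlation). Tapbp, which encodes the peptide loading factor tapasin, rose 4.83-fold and H2-Q4 5.81-fold. All 44 interferon-stimulated genes were higher than in control, with a median of 1.77 (adjusted p = 2.93e-53, adjusted p = 0.0644 with an estimated correlation). In this list Gbp2 rose 5.15-fold, from 45.0 ± 1.38 to 232 ± 7.98 CPM, and Gbp5 25.6-fold.

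In the sarcomere list, 48 of 50 genes were lower with TNF and 1 higher, with a median log2 fold change of -1.98 (adjusted p = 1.29e-20, adjusted p = 0.117 with an estimated correlation). Its members with the smallest p were Tpm2, at 1.68-fold lower, and the desmin gene Des, at 1.65-fold lower. Of 25 calcium handling genes, 24 were lower and 0 higher (median -1.63, adjusted p = 1.39e-16, adjusted p = 0.117 with an estimated correlation), including the acetylcholine receptor gene Chrna1 and the calcium channel gene Cacng1, at 1.93-fold and 1.99-fold lower. Energy metabolism genes were lower in 13 of 20 cases and higher in 1 (adjusted p = 0.000577, adjusted p = 0.117 with an estimated correlation), with log2 fold changes of -0.71 for Pfkm and -1.85 for Pgam2, both glycolytic enzymes. Of 12 myogenic regulators, 9 were lower and 1 higher (adjusted p = 4.23e-05, adjusted p = 0.117 with an estimated correlation), with Tead4 2.77-fold lower beside Myod1. In the fusion list 9 of 18 genes were lower and 3 higher (adjusted p = 0.00173, adjusted p = 0.260 with an estimated correlation), among them the cadherin gene Cdh15 (2.16-fold lower) and Dysf (2.74-fold lower).

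All 30 mitosis genes were higher with TNF than in control (median 0.87, adjusted p = 5.21e-19, adjusted p = 0.117 with an estimated correlation), including Bub1b at 1.97-fold and Top2a at 1.91-fold. DNA replication genes were higher in 35 of 36 cases and lower in 0 (median 0.77, adjusted p = 1.26e-12, adjusted p = 0.117 with an estimated correlation), with Mcm3 at 1.88-fold and Uhrf1 at 2.09-fold. Of 14 genes of cell cycle exit, 6 were lower and 5 higher (median -0.01, mean -0.24, adjusted p = 0.0305, adjusted p = 0.117 with an estimated correlation). The median was thus near 0, and Ccnd3, a cyclin gene induced in differentiating muscle, was 1.96-fold lower. That call was lost without the libraries of letter C (adjusted p = 0.0602). Cholesterol synthesis genes were higher in 24 of 25 cases and lower in 0, or in all 25 when adjusted over the list alone (median 0.78, adjusted p = 1.71e-13, adjusted p = 0.117 with an estimated correlation). Cyp51, which encodes a demethylase of sterol synthesis, rose 2.76-fold. The unfolded protein and stress response list had 20 of 25 genes higher and 1 lower (adjusted p = 0.0200, adjusted p = 0.155 with an estimated correlation), with log2 fold changes of 0.57 for Psat1 and 0.46 for Edem1.

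Repressors of myogenesis were lower in 13 of 26 cases and higher in 8 (adjusted p = 0.00404, adjusted p = 0.160 with an estimated correlation), with Id1, an inhibitor of MyoD-type factors, 2.18-fold lower. Hes6, a Hes family gene known to promote rather than repress myogenic differentiation, was 1.84-fold lower. Fibroblast markers were lower in 6 of 8 cases and higher in 1 (adjusted p = 0.00765, adjusted p = 0.117 with an estimated correlation). Dcn fell from 488 ± 16.1 to 119 ± 4.88 CPM and Lum, the lumican gene, from 1.08 ± 0.167 to 0.0711 ± 0.0392 CPM. Lum had only 6 counts in total over the TNF libraries, so the size of its fall is uncertain. All 4 adipocyte markers tested were lower (adjusted p = 0.0475, adjusted p = 0.117 with an estimated correlation), with Plin4 at 2.62-fold and Pparg at 1.92-fold, and that call was lost without the libraries of letter A (adjusted p = 0.0673).

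No call was made for 11 lists. The counts higher and lower were 15 and 12 of 40 for extracellular matrix, 7 and 8 of 25 for muscle atrophy and autophagy, 11 and 10 of 29 for genes related to Fbxl2, 9 and 7 of 21 for p53 targets, 11 and 12 of 27 for immediate early genes, and 12 and 4 of 26 for apoptosis. Among marker lists they were 4 and 7 of 12 for reserve or satellite cell markers, 2 and 4 of 7 for osteoblast markers, 4 and 2 of 7 for smooth muscle markers, 1 and 2 of 5 for macrophage markers and 0 and 1 of 1 for endothelial markers. Mean, median and test differed in sign for p53 targets, reserve or satellite cell markers and macrophage markers. Counts adjusted over the list alone were the same except for cholesterol synthesis as given, the unfolded protein and stress response (20 higher and 2 lower), genes related to Fbxl2 (12 and 10) and macrophage markers (2 and 2). In all, edgeR called 6960 of 12736 genes, of which 615 rose and 661 fell at least 2-fold. The calls split into 3954 higher and 3006 lower with TMM, and into 3214 higher and 3705 lower with upper-quartile scaling.

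**Figure D3:**
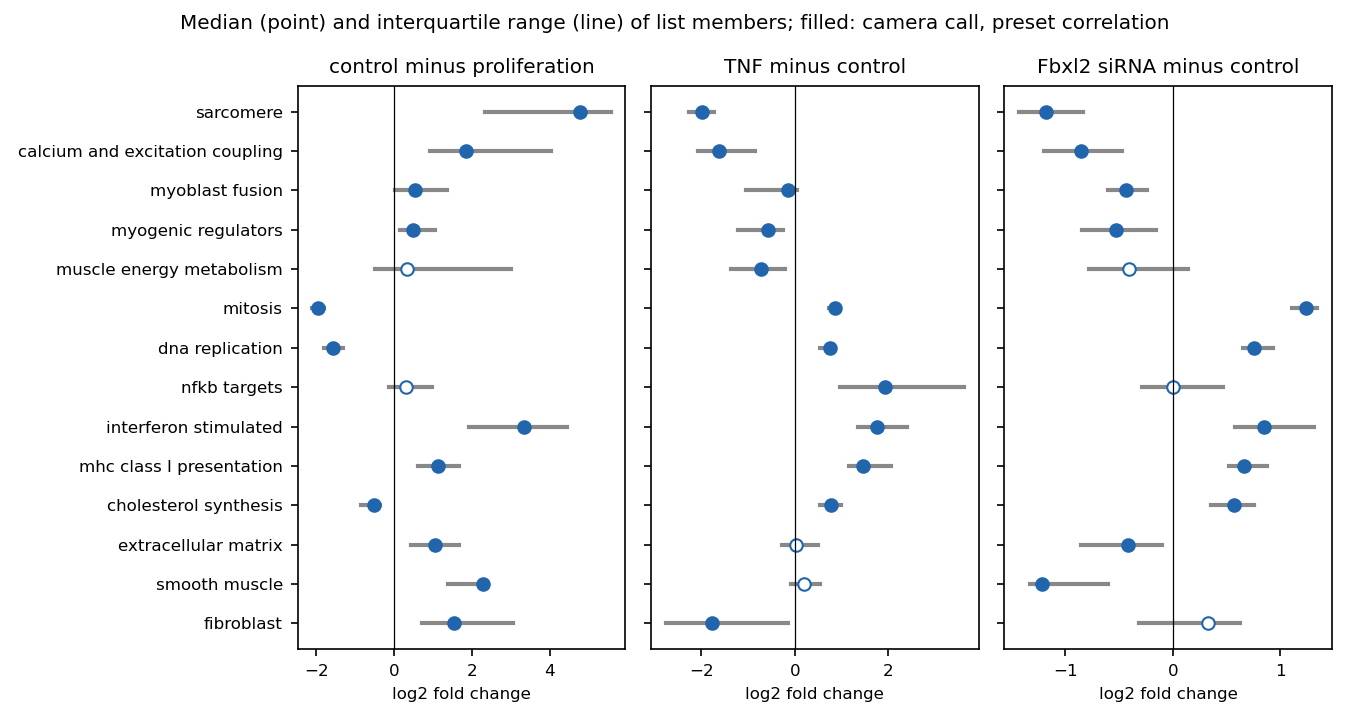
Median (points) and interquartile range (lines) of the log2 fold changes of list members in the 3 comparisons with or of control (panels, whose horizontal axes differ in range); filled points mark lists called by camera with the preset correlation. Sarcomere genes had medians of 4.78, -1.98 and -1.18, NF-kB targets 0.30, 1.94 and 0.00, and interferon-stimulated genes 3.34, 1.77 and 0.85.

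The third comparison asked what Fbxl2 silencing changed at 48 h of differentiation. Myog was 2.91-fold lower, at 104 ± 23.9 CPM against 302 ± 22 in control (SD, n = 3, log2 fold change -1.54, SE 0.17, adjusted p = 3.3e-05). Myh3 was 3.10-fold lower, at 238 ± 64.5 CPM, Mymk 2.78-fold, at 62.3 ± 14 CPM, and Myod1 1.77-fold, at 55.1 ± 2.73 CPM. Ckm was 1.71-fold lower and Cdkn1a 1.57-fold lower, while Mki67 was 1.90-fold higher, at 175 ± 8.70 CPM against 92.3 ± 6.80.

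The largest rises were those of Prl2c3, from 3.31 ± 0.214 to 338 ± 50.7 CPM, and Prl2c2, from 1.59 ± 0.286 to 151 ± 29.5 CPM, whose reads could be divided among near-identical copies. The family summed to 498 ± 81.8 CPM after Fbxl2 siRNA, against 5.17 ± 0.244 CPM in control and 675 ± 87.0 CPM in proliferating myoblasts. Sprr1a, a gene of the cornified envelope, rose 37.9-fold, the serpin gene Serpinb2 24.3-fold and Hdc, which encodes the enzyme that makes histamine, 18.9-fold. The largest falls were in the collagen genes Col8a2 (37.2-fold lower) and Col23a1 (22.8-fold), the chemokine scavenger receptor gene Ackr4 (21.4-fold), Fbln7 (15.3-fold) and Fam43a (7.53-fold). Nfkbia stood at 22.2 ± 1.40 CPM against 23.5 ± 1.64 in control (log2 fold change -0.08, SE 0.06, adjusted p = 0.255), and NF-kB targets had 14 members higher and 14 lower of 46, with no call.

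All 30 mitosis genes were higher after Fbxl2 siRNA, with a median log2 fold change of 1.24 (adjusted p = 9.21e-44, adjusted p = 0.0663 with an estimated correlation). The centromere histone gene Cenpa rose 3.07-fold and Ccnb1, the cyclin B1 gene, 2.72-fold. DNA replication genes were higher in 34 of 36 cases and lower in 0 (median 0.76, adjusted p = 3.38e-15, adjusted p = 0.198 with an estimated correlation), with Uhrf1 at 2.14-fold and the ligase gene Lig1 at 1.81-fold. In the sarcomere list 45 of 50 genes were lower and 2 higher (median -1.18, adjusted p = 2.35e-07, adjusted p = 0.380 with an estimated correlation), including Xirp1 at 3.90-fold and Klhl40 at 2.92-fold lower. Calcium handling genes were lower in 21 of 25 cases and higher in 1 (median -0.85, adjusted p = 8.17e-07, adjusted p = 0.307 with an estimated correlation), with Jph1, the junctophilin gene, 2.22-fold and Ryr3 2.69-fold lower. Of 18 fusion genes, 15 were lower and 1 higher (adjusted p = 6.04e-05, adjusted p = 0.285 with an estimated correlation), with the cadherin gene Cdh2 1.86-fold and Dysf 2.04-fold lower. Of 12 myogenic regulators, 10 were lower and 1 higher (adjusted p = 0.00229, adjusted p = 0.285 with an estimated correlation), and Pax7 was 2.11-fold lower.

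Interferon-stimulated genes were higher in 42 of 44 cases and lower in 0 (43 higher when adjusted over the list alone), with a median of 0.85 (adjusted p = 5.6e-14, adjusted p = 0.285 with an estimated correlation). Zbp1, a nucleic acid sensor, rose 3.65-fold and the RNA sensor gene Ifih1 1.99-fold. Genes of MHC class I presentation were higher in 20 of 21 cases and lower in 0 (median 0.66, adjusted p = 1.86e-09, adjusted p = 0.198 with an estimated correlation), with Tapbp at 2.32-fold and Psme2 at 1.84-fold. Cholesterol synthesis genes were higher in 23 of 25 cases and lower in 1 (median 0.57, adjusted p = 9.94e-08, adjusted p = 0.285 with an estimated correlation), with Fdps at 2.01-fold and Insig1 at 2.25-fold.

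Smooth muscle markers were lower in 6 of 7 cases and higher in 0, with a median of -1.22, and this call held with an estimated correlation (adjusted p = 0.0416). Acta2 fell from 2990 ± 74.4 to 1700 ± 62.6 CPM and Tagln from 488 ± 20.5 to 203 ± 2.47 CPM. Of 40 extracellular matrix genes, 28 were lower and 8 higher (adjusted p = 2.14e-06, adjusted p = 0.307 with an estimated correlation), with Thbs1, the thrombospondin gene, down from 2700 ± 48.3 to 900 ± 64.0 CPM. Repressors of myogenesis were lower in 17 of 26 cases and higher in 4 (adjusted p = 0.00100, adjusted p = 0.285 with an estimated correlation), including Id3 at 3.26-fold and Bhlhe41 at 2.32-fold.

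No call was made for 15 lists, NF-kB targets among them. For the others, the counts higher and lower were 6 and 9 of 20 for muscle energy metabolism, 5 and 7 of 14 for cell cycle exit, 4 and 15 of 25 for muscle atrophy and autophagy, 12 and 12 of 29 for genes related to Fbxl2, 8 and 6 of 21 for p53 targets, 12 and 3 of 25 for the unfolded protein and stress response, 8 and 13 of 27 for immediate early genes, and 12 and 8 of 26 for apoptosis. Among marker lists they were 3 and 4 of 12 for reserve or satellite cell markers, 4 and 2 of 8 for fibroblast markers, 1 and 1 of 4 for adipocyte markers, 3 and 2 of 7 for osteoblast markers, 1 and 2 of 5 for macrophage markers and 0 and 0 of 1 for endothelial markers. Mean, median and test differed in sign for genes related to Fbxl2, p53 targets, osteoblast markers and macrophage markers, and NF-kB targets had a median of 0.00, or -0.01 with 1 member at its bound, and a mean of 0.14. Counts adjusted over the list alone were the same except for interferon-stimulated genes as given, myogenic regulators (2 higher and 10 lower), calcium handling (1 and 22), energy metabolism (6 and 10), genes related to Fbxl2 (12 and 13) and immediate early genes (9 and 13). In all, edgeR called 8142 of 12736 genes, of which 641 rose and 646 fell at least 2-fold. The calls split into 4346 higher and 3796 lower with TMM, into 3984 and 4140 with RLE scaling, 3785 and 3867 with DESeq2, and 3944 and 4150 with no filter on low counts. The labels do not say whether the control cells were transfected, so this comparison holds the effects of transfection if they were not. If they were, the differentiation comparison holds them, its interferon-stimulated genes included.

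The direct contrast of TNF with Fbxl2 siRNA asked where both treatments differ. It leaves out the control means, though the control libraries still enter the filter, the scaling and the estimated spread. The labels do not say whether the TNF cells were transfected, so this contrast holds the effects of transfection if they were not. The largest rises in TNF were those of C3, at 753 ± 45.6 CPM against 0.166 ± 0.0335 after Fbxl2 siRNA (SD, n = 3), and of Saa3, with 147 ± 17.5 CPM against 3 counts over the siRNA libraries, a ratio of 4100 (95% counting interval 1400 to 19900). Tnip3 had a ratio of 1730 (310 to 68400) against 1 count, and Cxcl11 and the endothelial gene Ecscr had ratios of 343 (117 to 1670) and 286 (97.7 to 1390) against 3 counts each. The genes that were lowest in TNF against Fbxl2 siRNA were Prl2c3 and Prl2c2 (92.6-fold and 75.8-fold lower), Sprr1a (49.1-fold), the casein gene Csn3 (30.4-fold) and Rgs2, a regulator of G protein signalling (23.9-fold). Of 46 NF-kB targets, 45 were higher with TNF and 1 lower, a call that held with an estimated correlation (adjusted p = 0.000115).

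In this contrast smooth muscle markers were higher with TNF in 6 of 7 cases and lower in 0, which also held (adjusted p = 0.0175 with an estimated correlation). Interferon-stimulated genes were higher in 37 of 44 cases and lower in 1 (median 0.63, adjusted p = 1.62e-13, adjusted p = 0.415 with an estimated correlation), and genes of MHC class I presentation in 20 of 21 and 1 (adjusted p = 4.78e-14, adjusted p = 0.113 with an estimated correlation). Extracellular matrix genes were higher in 28 of 40 cases and lower in 9 (adjusted p = 7.95e-07, adjusted p = 0.415 with an estimated correlation). Sarcomere genes were lower with TNF in 40 of 50 cases and higher in 0 (median -0.80, adjusted p = 0.00015, adjusted p = 0.687 with an estimated correlation), calcium handling genes lower in 17 of 25 and higher in 3 (adjusted p = 0.00327, adjusted p = 0.687 with an estimated correlation), and mitosis genes lower in 25 of 30 and higher in 0 (median -0.37, adjusted p = 9.79e-05, adjusted p = 0.687 with an estimated correlation). Energy metabolism genes were lower in 13 of 20 and higher in 1 (adjusted p = 0.0487, adjusted p = 0.526 with an estimated correlation), fibroblast markers lower in 7 of 8 and higher in 1 (adjusted p = 0.00108, adjusted p = 0.136 with an estimated correlation), and osteoblast markers lower in 4 of 7 and higher in 1 (adjusted p = 0.0487, adjusted p = 0.230 with an estimated correlation).

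The energy metabolism call was lost without the libraries of letter A (adjusted p = 0.0728), and the osteoblast call without those of letter A (0.0821), B (0.0683) or C (0.0525). No call was made for 16 lists. The counts higher and lower were 3 and 7 of 12 for myogenic regulators, 10 and 7 of 18 for fusion, 5 and 9 of 36 for DNA replication, 3 and 7 of 14 for cell cycle exit, 9 and 13 of 26 for repressors of myogenesis, 11 and 6 of 25 for muscle atrophy and autophagy, 11 and 8 of 29 for genes related to Fbxl2, 8 and 9 of 21 for p53 targets, 8 and 4 of 25 for the unfolded protein and stress response, 14 and 4 of 25 for cholesterol synthesis, 10 and 9 of 27 for immediate early genes, and 10 and 7 of 26 for apoptosis. Among marker lists they were 6 and 5 of 12 for reserve or satellite cell markers, 0 and 4 of 4 for adipocyte markers, 1 and 1 of 5 for macrophage markers and 0 and 1 of 1 for endothelial markers. Mean, median and test differed in sign for cell cycle exit, repressors of myogenesis, p53 targets, immediate early genes and macrophage markers. Counts adjusted over the list alone were the same except for sarcomere genes (0 higher and 41 lower), DNA replication (4 and 7), interferon-stimulated genes (38 and 1), muscle atrophy and autophagy (12 and 6), cholesterol synthesis (15 and 4) and osteoblast markers (2 and 4). In all, edgeR called 7705 of 12736 genes, of which 692 were higher and 660 lower with TNF by at least 2-fold. The calls split into 3814 higher and 3891 lower with TMM, and into 3111 higher and 4717 lower with upper-quartile scaling.

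The effects of both treatments were set against those of differentiation. Of the 1537 genes that rose at least 2-fold in differentiation, TNF lowered 847 (55.1%) and raised 322 (20.9%), and Fbxl2 siRNA lowered 1079 (70.2%) and raised 141 (9.17%). Of the 1051 genes that fell at least 2-fold, TNF raised 661 (62.9%) and lowered 71 (6.76%), and Fbxl2 siRNA raised 892 (84.9%) and lowered 7 (0.666%). Among all 12736 genes, TNF raised 3954 and lowered 3006, and Fbxl2 siRNA raised 4346 and lowered 3796. The sets were chosen on the control libraries that both treatments were compared with, which favours opposite directions by construction.

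Across the 12736 genes, which are not independent replicates, the log2 fold changes of Fbxl2 siRNA and of differentiation had a Pearson correlation of -0.66 and a Spearman correlation of -0.72. These comparisons share the control libraries with opposite signs, and simulated unchanged groups had a mean Pearson correlation of -0.50 (-0.65 to -0.34 over 100 draws). The covariance was -0.543 against a simulated -0.0196. For TNF and differentiation the Pearson correlation was -0.29 and the Spearman correlation -0.42, with a simulated Pearson mean of -0.49 (-0.61 to -0.36), and the covariance was -0.267 against a simulated -0.0192. For TNF and Fbxl2 siRNA, which share the control libraries with the same sign, the Pearson correlation was 0.35 and the Spearman correlation 0.43, with a simulated Pearson mean of 0.49 (0.25 to 0.62), and the covariance was 0.189 against a simulated 0.0191. Unchanged groups that share controls correlate by construction, whatever the size of their noise. The simulated Pearson values are therefore no reference for data with many changed genes.

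Both TNF and Fbxl2 siRNA raised 2285 genes and both lowered 1737, where independent lists of these sizes would share 1349 and 895.9. TNF raised and Fbxl2 siRNA lowered 609 genes, and 451 went the other way, where independent lists would share 1179 and 1026. Fbxl2 siRNA raised 3413 genes that fell in differentiation and lowered 3060 that rose, against 1689 and 1456 for independent lists, and TNF raised 2410 and lowered 2117 such genes, against 1537 and 1153. The simulated draws held no changed genes, so their highest overlap of 1 gene gives no reference for lists of these sizes. With 3 control libraries the controls could not be split with at least 2 libraries in each part, so part of the excess may come from the shared controls.

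**Figure D4:**
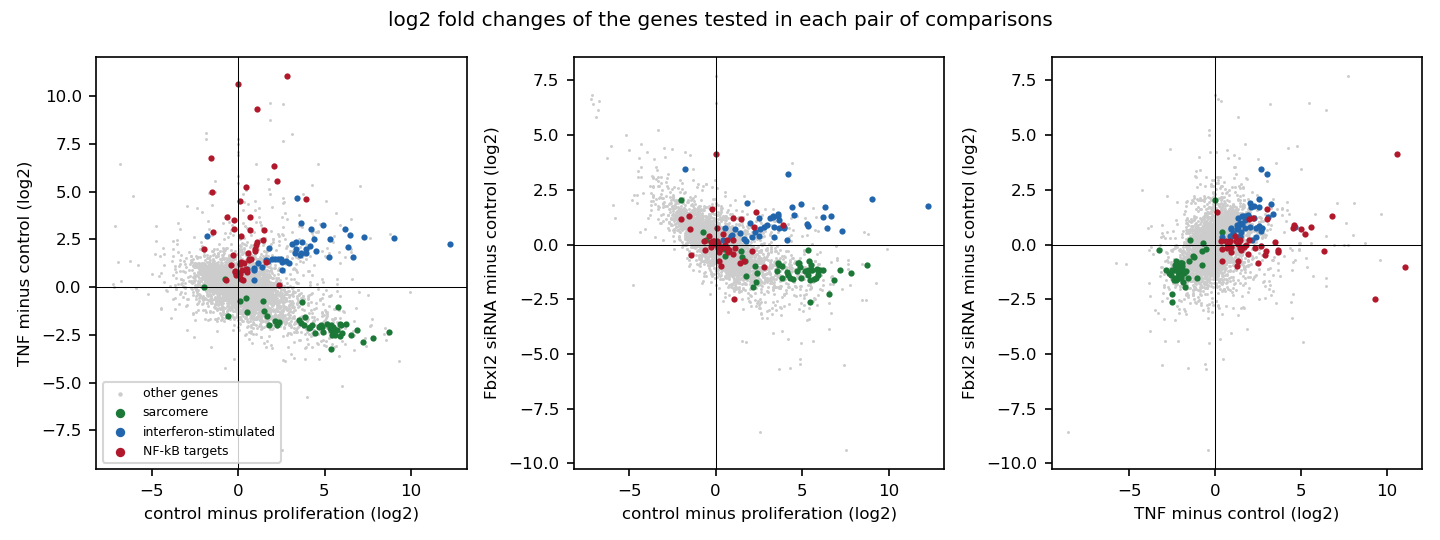
Fitted log2 fold changes of the 12736 genes in each pair of comparisons (axes), with sarcomere genes in green, interferon-stimulated genes in blue, NF-kB targets in red and other genes in grey. Sarcomere genes lie at mostly positive values in differentiation and mostly negative values in both treatments (medians 4.78, -1.98 and -1.18), and interferon-stimulated genes at mostly positive values in all 3 comparisons (medians 3.34, 1.77 and 0.85).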

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

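No named gene, list call or correlation reversed its direction under the alternatives it was run with, and all were planned. Lists were rerun only with an estimated correlation, fry, RLE scaling, the replicate block and without a whole letter. Correlations were rerun only with RLE scaling, DESeq2, the filter of 1 CPM, the replicate block and without single replicates. Whether more calls were higher or lower did turn: for TNF and for Fbxl2 siRNA as given above, and under several settings for differentiation (4885 higher and 4951 lower, against 4991 and 4816 with RLE scaling) and TNF against Fbxl2 siRNA (3814 and 3891, against 3993 and 3705). No gene called in both fits changed direction. Counts of called genes stayed within 1.5 times those reported in 68 cases. The other 4 were those of the 2-fold threshold, which left 2588 genes for differentiation, 1276 for TNF, 1287 for Fbxl2 siRNA and 1352 for TNF against Fbxl2 siRNA, fewer by construction. Leaving out replicates gave 8582 to 9785, 5000 to 6609, 6450 to 7852 and 5701 to 7370 genes in these comparisons, with fewer samples in each fit. The correlation of TNF effects with differentiation moved from -0.29 to -0.25 with the filter of 1 CPM in 3 libraries, where fewer genes were tested, and ranged from -0.31 to -0.28 without single replicates. Those of Fbxl2 siRNA with differentiation and of TNF with Fbxl2 siRNA ranged from -0.66 to -0.63 and from 0.32 to 0.38. Values of named genes stayed on their side of the threshold in 2474 cases and lost the call in 8, those of Nfkbia in differentiation and Fbxl2 with TNF given above. List results stayed on their side of the threshold in 656 cases. With an estimated correlation 45 list calls were lost and 9 held, and fry, which tests another hypothesis, added 40. The other calls gained were muscle atrophy with Fbxl2 siRNA with RLE (adjusted p = 0.0499) and without letter A (0.0326), the unfolded protein list with Fbxl2 siRNA without A (0.0215), and in differentiation energy metabolism without C (0.0396) and repressors without B (0.0447). Over all groups the letters showed no clear pairing: 3 of 18 same-letter correlations of deviations exceeded 0.1 (-0.0957 to 0.183), and the same letter correlated best in 12 of 36 cases. Between proliferation and Fbxl2 siRNA the same-letter values were 0.124 (A), 0.115 (B) and 0.0638 (C). Those of unlike letters ran from -0.135 to 0.019, so pairing of these groups stays open. No other pair of groups was alike in this. The replicate block gave 9897, 7070, 8239 and 7833 genes and ended 2 list calls, adipocyte markers with TNF (adjusted p = 0.0753) and osteoblast markers in TNF against Fbxl2 siRNA (0.0546). A term for letter A gave 9930, 7102, 8266 and 7866 genes. Letter A on its own holds 1 library per group, so no value within it was tested. DESeq2 gave 9621, 6459, 7652 and 7277 genes. Depth limited the folds of genes with 1 to 3 counts in a group to wide counting intervals, such as 197 to 43600 for Cxcl11 with TNF.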

Other observations

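The tests of shared controls, mixed cells, scaling, transfection, divided reads and other splits, and the levels relative to both ends of differentiation, were chosen or set down only after the results were seen. The levels of Fbxl2 siRNA and TNF libraries were placed against both ends of differentiation. After Fbxl2 siRNA, 1032 of 12736 genes were called higher, and 890 lower, than in both proliferation and control libraries, and with TNF these counts were 1673 and 1047. The way back from control to proliferation was computed on mean CPM, not on log2 values. Of the sarcomere genes that changed at least 2-fold in differentiation, the median siRNA level lay 58.5% of the way back from control to proliferation (quartiles 53.7% and 68.3%, 45 genes) and the median TNF level 80.3%. For mitosis genes these medians were 47.7% and 28.6%, so the order of the treatments differed between these lists (not tested as an interaction, though the direct contrast called both lists lower with TNF at the preset correlation only). For smooth muscle markers they were 69.1% and -33.8%, the negative value meaning a level beyond control. In log2, over all tested members, the siRNA median was -24.6% of the differentiation median for sarcomere genes. It was -63.7% for mitosis and -48.4% for DNA replication genes. With TNF these values were -41.4%, -44.7% and -49.2%. The order of these lists within a treatment therefore depended on the scale. Fibroblast markers were above both ends for 4 of 8 genes after Fbxl2 siRNA and for 1 of 8 with TNF.

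Fbxl2 siRNA effects ran against those of differentiation. Independent noise of the control libraries, which both comparisons share, was tested by simulation. The covariance of -0.543 lay below the lowest of 100 simulated values (-0.0315), so such noise alone does not account for it. A deviation common to all control libraries would also enter both comparisons with opposite signs. The simulated libraries all followed the control means, so the draws held no such deviation and cannot decide on it. A single mix of cells like the proliferation libraries and cells like the control libraries would place every gene between both, but 42 of 44 interferon-stimulated genes lay above both ends. That was already implied by their rise in differentiation and their further rise after Fbxl2 siRNA. It cannot decide against a mix with a response to transfected RNA on top, which could raise the same genes. A single mix would also give sarcomere and DNA replication genes the same percent of the way back in CPM. Their medians differed by 21 points, and the quartiles over genes did not overlap (53.7% to 68.3% against 32.2% to 41.9%). These quartiles come from group means of genes that are not independent, so they do not measure the spread between libraries. The gap was not tested against that spread. The proliferation end was measured in growth medium at 0 h, and no group was kept proliferating to 48 h. A mix with such cells was therefore not tested. The effect of transfection, or of another target of the siRNA, cannot be told apart from that of Fbxl2, because 0 labels name a non-targeting siRNA and Fbxl2 RNA was still at 67.5% of control.

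After Fbxl2 siRNA, 42 of 44 interferon-stimulated genes were called higher than in control (adjusted p = 0.285 for the list with an estimated correlation). Scaling between libraries does not account for it, since the lower of the list medians with RLE and upper-quartile scaling was 0.82 against 0.85 with TMM. A response to transfected RNA could raise such genes, and it cannot be told apart from an effect of Fbxl2 because 0 labels name a non-targeting siRNA. In differentiation, which would hold a transfection effect too if the control cells were given a non-targeting siRNA, 43 of 44 were higher and 1 lower (adjusted p = 0.0794 with an estimated correlation), and with TNF 44 of 44 were higher (adjusted p = 0.0644 with an estimated correlation).

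The Prl2c genes were high in proliferating myoblasts and after Fbxl2 siRNA, and low in control and TNF libraries. Reads divided differently among the near-identical copies would leave their sum alike, but the summed CPM was 96.3 times higher after Fbxl2 siRNA than in control, with libraries of 428, 588 and 478 against 5.21, 4.91 and 5.39 CPM. The siRNA sum was 498 ± 81.8 CPM against 675 ± 87.0 in proliferation and 5.87 ± 0.813 with TNF. Transfection stays open here too, for the reason given above.

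Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split called 9836 genes for differentiation, 6960 for TNF, 8142 for Fbxl2 siRNA and 7705 for TNF against Fbxl2 siRNA, and in each 1 split, the real one, called as many with edgeR. The highest other split called 0 genes in each. Every other split put libraries of both groups on each side, so the group difference itself widened the spread. These values of 0 therefore do not measure how many calls arise without an effect.

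In the authors' deposited tables, an adjusted p under 0.05 was given for 6661 genes for TNF over control and 7756 for Fbxl2 siRNA over control. Of the genes found in both the authors' deposited table and the edgeR fit, 6206 and 7477 were called by both in the same direction and 0 in opposite directions.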
